A study of Mus musculus with 14 samples.

How the data were processed

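RNA sequencing was done on inguinal fat, a subcutaneous depot, of 14 C57BL/6J mice in 4 groups that cross a transgene with a drug infusion. Non-transgenic mice received saline (CON, 3 libraries) or CGP, an agonist of the angiotensin type 2 receptor (CON_CGP, 4 libraries). SRA mice, transgenic mice whose brain renin-angiotensin system is switched on, received saline (SRA, 3 libraries) or the same agonist (SRA_CGP, 4 libraries). Each library was taken as 1 mouse, with the group, replicate number and sex from the labels. CON held 2 males and 1 female, SRA 1 male and 2 females, and both agonist groups 2 males and 2 females.

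Total RNA was isolated with Trizol and an RNeasy column, treated with DNase and made into indexed Illumina libraries, per the labels' protocols. FastQC, Bowtie, edgeR and the mouse build mm9 were named, per the submitters' processing notes. Their versions and roles, the counting of reads and the method of normalization are not given in the sources used here. The deposited table gave 1 score per transcript and library, which the authors' header calls a normalized count. These values are whole numbers for 55419 UCSC known-gene transcripts, of which 7183 were at 0 in all 14 libraries. Each column was tied to its mouse through the number in the sample description, and 0 columns were left without a sample. All 14 columns summed to between 79970748 and 79985973, a spread of 0.019%, so the totals carried no depth. Low values were searched, over a limited range of step sizes, for a fixed step that would give back whole reads. The best step took in 41.6% to 53.8% of the values up to 40 in a library, within a tolerance of 0.5 of a unit. Whole reads were therefore not recovered, the sequencing depth is unknown, and no interval or floor from read counts is given. Steps outside that range were not tried and no value by chance was taken, so a step may have been missed. For the same reason the count models planned with edgeR and DESeq2 were not used.

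The files do not pair transcript IDs with gene names, and 0 IDs matched a symbol in the tables used here. Transcripts are named by ID alone. The planned gene lists, the camera and fry tests on them, the cell type markers, the fixed set of genes to name and the alternative with a B cell term were not run. Several transcripts of 1 gene can share reads, and how the authors' counting divided them is not given in the sources used here. Of the tested transcripts, 10972 (27.5%) had a near-identical neighbour in the table, within 0.1 log2 units in every library, and merging these left 33452 clusters.

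Values were analysed as log2(value + 1), so fold changes are on that scale and understate the change of transcripts with low values. Transcripts with a mean of at least 10 over the 14 libraries were tested, which left 39956 of them (72.1%) holding 99.97% of the total. The main test was limma 3.58.1 in R 4.3.3, with 1 term per group and a term for sex, and with variance moderation that was robust and followed mean abundance. All 14 libraries entered 1 fit, and 2-sided p-values were adjusted by the Benjamini-Hochberg method over all tested transcripts, with a threshold of 0.05. Contrasts were the transgene under saline and under CGP, the agonist in each genotype and averaged over both, their interaction, sex, and the interactions of sex with the agonist and the transgene. These contrasts, the filter, the pseudocount and the sex term were fixed before the data were examined. The transgene contrast averaged over both infusions was added afterwards.

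Transcripts to name were set by a rule fixed before the data were examined. Among calls with a mean of at least 100, the largest rises and falls were taken. Where fewer than 5 transcripts passed, those with the smallest p in each direction were taken and are said not to have passed. At most 2 IDs per direction are printed for a comparison. A comparison with a single call below that mean is named by that call, which was chosen after its values were seen.

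The test was checked on simulated data with the spread of the real transcripts. For SRA against CON under saline, with 39956 simulated transcripts, limma called 40% of those changed 2-fold and 67% of those changed 4-fold, with 3 false calls. For SRA against CON under CGP, also with 39956 transcripts, it called 54% and 74%, with 6 false calls. Noise was drawn independently for each transcript there, whereas transcripts in the real libraries vary together, which the simulation left out.

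Groups share replicate numbers in the labels, which do not say what a number stands for. Whether same-numbered libraries deviated together from their group means, with sex removed, was checked for each comparison, with a correlation above 0.1 in every pair as the criterion for pairing. It was met for SRA against CON under saline (3 pairs, r from 0.131 to 0.316) and for CGP in SRA (3 pairs, 0.123 to 0.625), so values with the replicate number as a block are given beside both. It was not met for CGP in CON (-0.237 to 0.106) or SRA against CON under CGP (-0.262 to 0.565). In both comparisons that met it, same-numbered libraries were all of opposite sex, and in both others all of the same sex. Taking out group means and sex makes such deviations correlate by itself, upwards for opposite sexes. A fixed bound of 0.1 therefore cannot tell pairing from the sex layout. Any pairing thus comes from the data alone, with few pairs. The criterion was first applied to all groups together and then per comparison, after the counts with the block had been seen.

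Library pairs were compared by Pearson correlation of log2 values. The 18 pairs within a group had a median r of 0.942 (0.863 to 0.985) and the 73 pairs across groups 0.938 (0.851 to 0.988), and 0 pairs were identical. Alternatives covered the pseudocount, the filter, the scaling, the sex term, the replicate number as a block, the groups in the fit, the variance moderation, array weights, each library left out in turn, and 6 libraries left out together. Principal components were taken on the log2 values, and their scores were compared by exact permutation tests.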

Results

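Transcript levels were measured by RNA sequencing in the inguinal fat of 14 mice, 7 without and 7 with the SRA transgene, which activates the renin-angiotensin system of the brain. Within each genotype some mice received saline (6 in all) and some CGP, an agonist of the angiotensin type 2 receptor (8 in all). The groups were CON (n = 3), SRA (n = 3), CON_CGP (n = 4) and SRA_CGP (n = 4), and 7 mice were male and 7 female. The series concerns angiotensin type 2 receptors in fat and heat production. Values are the deposited normalized values, scaled to nearly the same total in each library (79970748 to 79985973), and sequencing depth is unknown. Transcripts carry UCSC IDs of the mm9 build, and the files do not pair them with gene names.

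The libraries differed along a first principal component that held 37.4% of the variance, and a second that held 22%. Scores on the first were higher in the 7 transgenic mice (47.7 ± 86.4, SD, n = 7) than in the 7 others (-47.7 ± 61.1, SD, n = 7; exact permutation p = 0.0373, adjusted over 6 tests 0.0746). They were also higher in females (48.5 ± 65.9, SD, n = 7) than in males (-48.5 ± 81.8, SD, n = 7; exact permutation p = 0.0338, adjusted 0.0746). Neither passed after adjustment. Mean scores on the second were lower in females (-46.4 ± 47.3) than in males (46.4 ± 49.4, SD, n = 7 each, exact permutation p = 0.0035, adjusted 0.021). The sexes overlapped there, as the female SRA_CGP replicate 3 lay at 41.9 and the male CON replicate 1 at 10.4. Agonist and saline libraries did not differ on either component at the threshold, with exact permutation p = 0.748 and 0.76.

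**Figure D1:**
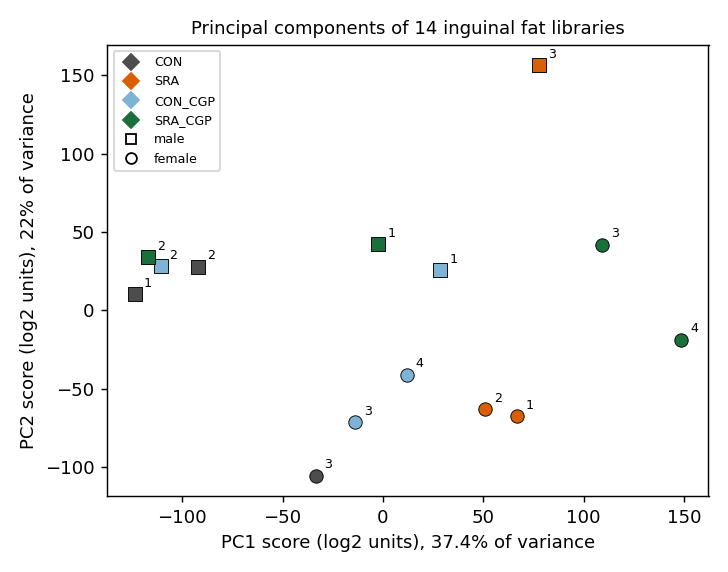
Scores of the 14 libraries on the first (x axis) and second (y axis) principal components of log2 values, in log2 units, with colour for group, squares for males, circles for females and the replicate number beside each point. Along the first component libraries lie between -123.7 and 148.6, and SRA_CGP libraries alone lie between -116.8 and 148.6.

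The first comparison asked how fat of SRA mice differed from that of non-transgenic mice under saline. The transcripts with the smallest p were higher in SRA by 3.31 ± 0.52 (log2, SE) for uc012cti.1 and 2.55 ± 0.42 for uc007ucx.2. Group means of uc012cti.1 were 49.7 ± 44.6 in CON and 941 ± 757 in SRA (SD, n = 3 each). Its SRA values were 1081 and 1618 in the females and 123 in the male. uc007jqx.1 was lower in SRA by a log2 difference of -1.6 ± 0.25, at 1440 ± 91.7 in CON and 457 ± 90.7 in SRA (SD, n = 3 each). uc012civ.1 differed by -0.95 ± 0.15, at 555 ± 110 and 310 ± 36 (SD, n = 3 each). In the fit of all groups without a replicate block none of the 4 passed, as limma gave each an adjusted p of 0.13, the smallest of the comparison. All 4 passed in the fit of the 6 saline libraries alone (limma adjusted p = 0.0221), and without SRA replicate 3 uc012cti.1 (0.0259) and uc007ucx.2 (0.0229) did, at log2 differences of 4.03 and 3.18. Without the 6 libraries described with the sex comparison all 4 had a limma adjusted p of 1, at log2 differences of 3.78, 3.48, -0.8 and -0.81. Only males were then left in CON and only females in SRA. With the replicate number as a block all 4 passed, at log2 differences of 3.15, 2.39, -1.68 and -0.95 in the same order and limma adjusted p from 0.0297 to 0.0361. The criterion behind that block cannot tell pairing from the sex layout, so values with the block rest on a pairing that is not known.

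Across all 39956 transcripts limma without the block called 0 between SRA and CON under saline, and with the block 532, 362 higher and 170 lower in SRA. Without the block 9138 (22.9%) had an unadjusted p under 0.05, against 1998 by chance. That number was 2943 without CON replicate 3 (only males left in CON), 3896 without SRA replicate 3 (only females left in SRA) and 4932 without CON replicate 1. It rose to 10920 without CON replicate 2, 10378 without CON_CGP replicate 1 and 11931 without SRA_CGP replicate 2, the highest without 1 library. Without the same 6 libraries it was 1007. The last fit had fewer libraries, with only males in CON and only females in SRA, so it does not tie the excess to those 6. Of the 9138, 2113 were higher and 7025 lower in SRA, and the median log2 difference of all transcripts was -0.249. The direction followed the scaling. The share that was lower was 76.9% with the deposited values, 27.8% after median-of-ratios rescaling and 46.6% after quantile normalization, and the median moved to 0.028 and -0.034. The count of calls followed the fit. A fit of the 6 saline libraries alone called 9725 transcripts, and without SRA replicate 3 the fit of all groups called 13.

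The same genotype contrast under CGP asked whether transgenic and non-transgenic mice differed when both received the agonist. One transcript, uc008qvw.2, was higher in SRA_CGP than in CON_CGP, at 69 ± 17.7 against 11.8 ± 5.68 (SD, n = 4 each). The log2 difference was 2.51 ± 0.26 (SE), or 5.7-fold, with a limma adjusted p of 0.0267. It was also at 68.3 ± 15.5 in SRA and 15.3 ± 1.15 in CON (SD, n = 3 each), where limma gave a log2 difference of 2.25 and an adjusted p of 0.13. Over both infusions it lay between 8 and 20 in the 7 non-transgenic mice and between 45 and 86 in the 7 transgenic mice, without overlap. Its mean of 41 was below the level set for naming, and it was singled out after its values were seen. Array weights apart, the call held in 7 of 24 alternatives, whose adjusted p ranged from 0.0101 to 0.594. Among single libraries left out, it held without CON_CGP replicate 2 (0.0208) and was lost without each of the other 13, at adjusted p from 0.0522 to 0.198. The log2 difference lay between 2.41 and 2.71 in the fits without 1 library, and between 2.14 and 2.97 over the 24 alternatives.

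**Figure D2:**
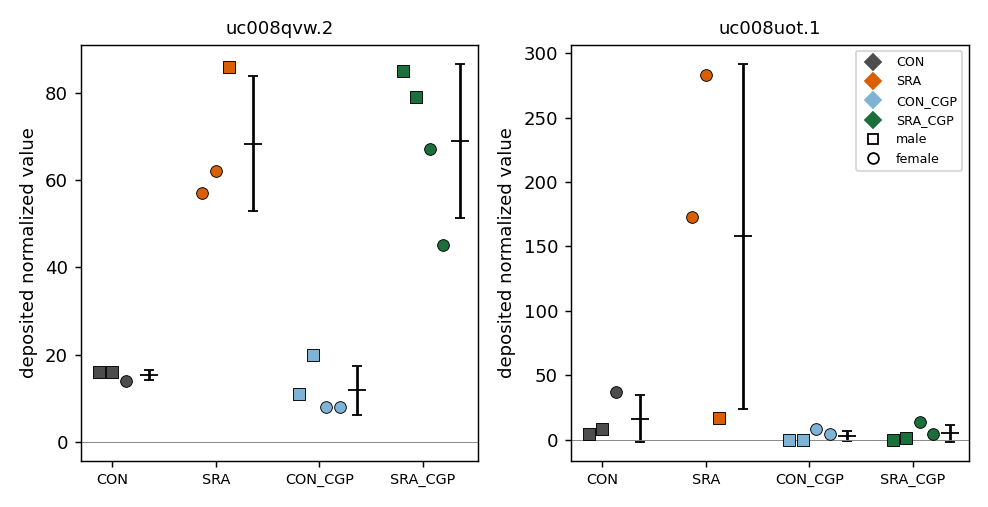
Deposited normalized values (y axis) of uc008qvw.2 and uc008uot.1 in each library, by group (x axis), with squares for males and circles for females; the bar beside each group is its mean ± SD (n = 3 or 4). For uc008qvw.2 the 7 transgenic mice lie between 45 and 86 and the 7 others between 8 and 20; for uc008uot.1 the SRA libraries lie at 173, 283 and 17.

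Other transcripts with small p under CGP did not pass. uc011wqt.1 and uc007ciz.1 were higher in SRA_CGP by 0.69 ± 0.13 and 0.72 ± 0.14 (log2, SE; limma adjusted p = 0.635). uc007thd.1 and uc011zjm.1 had log2 differences of -1.15 ± 0.17 and -1.13 ± 0.18 (limma adjusted p = 0.334). In all, 2685 transcripts had an unadjusted p under 0.05, 692 higher and 1993 lower. That number was 6101 without CON_CGP replicate 1, 6012 without SRA_CGP replicate 2, 1541 without CON_CGP replicate 3 and 1448 without SRA_CGP replicate 3. The share that was lower was 74.2% with the deposited values, 46% after median-of-ratios rescaling and 39.4% after quantile normalization. The median of all transcripts was -0.119, -0.014 and 0.011 in turn.

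Averaging the genotype contrast over both infusions, a comparison added after the separate ones were seen, gave 15 limma calls, 1 higher and 14 lower in transgenic mice, in 7 clusters of near-identical transcripts. uc011wve.1 fell, with a log2 difference of -1.52 ± 0.21 (SE), from 680 ± 24.1 in CON to 184 ± 126 in SRA (SD, n = 3 each), and stood at 669 ± 381 in CON_CGP and 248 ± 38.6 in SRA_CGP (SD, n = 4 each). uc007nur.1 fell likewise, with a log2 difference of -1.19 ± 0.17 (SE), from 406 ± 11.6 to 147 ± 32.5 (SD, n = 3 each), and stood at 441 ± 197 in CON_CGP and 193 ± 65.3 in SRA_CGP (SD, n = 4 each). Over both infusions its genotypes overlapped, with a lowest non-transgenic value of 247 and a highest transgenic value of 263. Both transcripts had a limma adjusted p of 0.0499. With the replicate number as a block limma called 937 transcripts. Both then had a limma adjusted p of 0.0288, at log2 differences of -1.49 and -1.22. The criterion for pairing was met for the saline part of this contrast and not for the CGP part. Unadjusted p was under 0.05 for 11383 transcripts, 2398 higher and 8985 lower. That number was 5625 without CON replicate 3 (only males left in CON) and 6544 without SRA replicate 3 (only females left in SRA). It was 2066 without the 6 libraries, near the 1998 of chance. The last fit had fewer libraries, with only males in CON and only females in SRA, so it does not tie the excess to those 6. With median-of-ratios rescaling and with quantile normalization 1 call was left, the one that was higher, so uc011wve.1 and uc007nur.1 lost theirs. The call left had a mean below the level set for naming, so it is not named. The smallest limma adjusted p among the 15 calls was 0.00314, well below that of the 2 named. Array weights apart, uc011wve.1 passed in 6 of 24 alternatives at log2 differences from -1.69 to -1.32, and uc007nur.1 in 5 of 24 at -1.31 to -0.98. Among single libraries left out, uc011wve.1 passed without CON replicate 2, SRA replicate 3 or SRA_CGP replicate 2, and uc007nur.1 without CON replicate 2 or SRA_CGP replicate 2. The lower share at p under 0.05 was 78.9% as deposited, 33.8% and 44.2%, and the median moved from -0.186 to 0.005 and -0.013. Calls rose to 1621 without CON replicate 2 and 4808 without SRA_CGP replicate 2, and fell to 1 without each of 11 other libraries.

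The agonist contrast within non-transgenic mice asked what CGP did without the transgene. The smallest p-values were those of uc007neq.1 and uc011yla.1, higher under CGP by 1.42 ± 0.32 and 1.37 ± 0.31 (log2, SE), and of uc012fzb.1 and uc007odi.1, with differences of -1.31 ± 0.24 and -0.46 ± 0.09. uc007odi.1 was at 1160 ± 92.4 in CON (SD, n = 3) and 854 ± 30 in CON_CGP (SD, n = 4). None passed, with a limma adjusted p of 0.948 for all 4. limma called 0 transcripts, and 1587 had an unadjusted p under 0.05, fewer than the 1998 expected by chance. Without CON_CGP replicate 1 they were 992 and without CON_CGP replicate 2 they were 2563. Of the 1587, 619 were higher and 968 lower; the lower share was 61% as deposited, 31.4% after median-of-ratios rescaling and 38.5% after quantile normalization.

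The agonist contrast within SRA mice asked the same with the transgene present. uc007cav.1 was higher under CGP by 1.05 ± 0.19 (log2, SE), from 1120 ± 290 in SRA (SD, n = 3), and uc011wph.1, whose values nearly copy it, by 1.05 ± 0.19 (limma adjusted p = 0.276 for both). uc012cti.1 had a log2 difference of -3.17 ± 0.47, from 941 ± 757 in SRA (SD, n = 3) to 62.2 ± 41.3 in SRA_CGP (SD, n = 4), with a limma adjusted p of 0.151. It was at 1081 and 1618 in SRA replicates 1 and 2, on which the fall mainly rested. In SRA replicate 3 it was at 123, close to the 23 to 116 of SRA_CGP. Array weights apart, it passed in 1 of 25 alternatives (limma adjusted p = 0.0134), and its log2 difference ran from -3.83 to -2.78. uc009aal.1 had a difference of -0.48 ± 0.08 (limma adjusted p = 0.195). limma called 0 transcripts without a replicate block and 15 with it, 1 higher and 14 lower. None of the 4 named passed with the block (adjusted p from 0.0737 to 0.148). Without it 2775 had an unadjusted p under 0.05, 1296 higher and 1479 lower, which became 4316 without SRA_CGP replicate 3 and 1847 without SRA_CGP replicate 1. The lower share was 53.3% as deposited, 65.6% after median-of-ratios rescaling and 38.1% after quantile normalization. Without SRA replicate 3, limma called 29.

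Whether the agonist response differed between the genotypes was tested by their interaction. limma called 0 transcripts, with 1592 at an unadjusted p under 0.05. These became 936 without CON replicate 3, 2602 without CON_CGP replicate 2 and 2666 without SRA_CGP replicate 3. The smallest p-values were those of uc008zhv.2 (1.12 ± 0.24, log2 difference of the responses, SE), uc007unt.1 (0.68 ± 0.15), uc009aal.1 (-0.53 ± 0.11) and uc012cti.1 (-2.89 ± 0.67), each with a limma adjusted p of 0.898. Over 24 alternatives, array weights apart, uc012cti.1 ran from -3.61 to -2.49 and uc007unt.1 from 0.33 to 0.77, and neither passed in any. The value of uc012cti.1 again rested mainly on SRA replicates 1 and 2. Of the 1592, 943 were higher and 649 lower; the lower share was 40.8% as deposited, 71.9% after median-of-ratios rescaling and 42.6% after quantile normalization. The median of all transcripts was 0.12 as deposited and -0.052 after median-of-ratios rescaling.

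Averaged over both genotypes, the agonist contrast gave 1 call. uc008uot.1 fell under CGP, with a log2 difference of -3.49 ± 0.37 (SE) and a limma adjusted p of 0.0396. Its mean was 158 ± 134 in SRA and 16.3 ± 18 in CON (SD, n = 3 each), against 4.75 ± 6.4 in SRA_CGP and 3 ± 3.83 in CON_CGP (SD, n = 4 each). Its SRA values were 173 and 283 in the females and 17 in the male, its overall mean of 39.5 was below the level set for naming, and it was singled out after its values were seen. Array weights apart, the call held in 4 of 23 alternatives, with adjusted p from 0.00929 to 0.736; among single libraries left out it held without SRA replicate 3 (0.00929) and was lost without each of the other 13, at adjusted p from 0.061 to 0.315. The log2 difference lay between -3.66 and -3.33 in the fits without 1 library, and was -2.41 and -4.46 with pseudocounts of 5 and 0.2. uc007kws.1 and uc008vye.1 were higher under CGP by 0.82 ± 0.13 and 0.75 ± 0.12 (log2, SE; limma adjusted p = 0.276), and did not pass. uc012fzb.1 and uc009aat.1 had differences of -0.98 ± 0.17 and -0.56 ± 0.1 (limma adjusted p = 0.276 and 0.315), and did not pass. In all, 2697 transcripts had an unadjusted p under 0.05, 1153 higher and 1544 lower. The lower share was 57.2% as deposited, 46.6% after median-of-ratios rescaling and 32.7% after quantile normalization. Without SRA replicate 3, limma called 30.

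Sex gave the most calls of the comparisons fixed before the data were examined. limma called 2120 transcripts between females and males, 1792 higher and 328 lower in females, in 1811 clusters of near-identical transcripts. uc009kba.1 and uc007okc.2 were higher in females by 6.13 ± 0.93 and 5.94 ± 0.7 (log2, SE; limma adjusted p = 0.00207 and 0.000583). uc009kba.1 overlapped between the sexes, at 6 to 813 in females and 0 to 9 in males, and uc007okc.2 did not, at 147 or more in females and at most 54 in males. Pseudocounts of 5 and 0.2 moved uc009kba.1 to 4.45 and 7.61. Without CON replicate 3 the differences were 5.45 and 5.19, and without the 6 libraries described next 5.54 and 6.6, where uc009kba.1 did not pass (limma adjusted p = 0.209). uc009uzn.2 and uc009uzm.2 were lower in females, with differences of -6.71 ± 1.08 and -6.66 ± 1.07 (limma adjusted p = 0.00313 and 0.00316). uc009uzm.2 lay between 5588 and 8657 in the 7 males and between 0 and 573 in the 7 females, whose higher values were in libraries that held other transcripts of males. Without the 6 libraries both differences were -8.02. They were -5.49 and -5.5 without SRA replicate 3, -6.12 and -6.06 without CON_CGP replicate 3, -7.39 and -7.33 without CON_CGP replicate 4, and -8.73 and -8.61 with the replicate number as a block. Without the 6 libraries, an alternative chosen after the data were seen, 597 transcripts were called, 572 higher and 25 lower in females. There the sex difference came from the CGP groups alone. With the replicate number as a block 2203 were called, 1296 higher and 907 lower, and 1258 of the main calls were kept.

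Transcripts seen almost only in 1 sex were present at a low level in some libraries of the other. The set held 12 male transcripts, at 100 or more in all 7 males, lower in every female and at most 1 in the lowest female, and 49 female transcripts chosen the same way. Their median level was above 2% of that in the other sex in 6 libraries, 3 female and 3 male. It was 5.18% in CON replicate 3, 4.47% in SRA replicate 3, 11.1% in CON_CGP replicate 1, 8.26% in CON_CGP replicate 4, 14.6% in SRA_CGP replicate 1 and 8.28% in SRA_CGP replicate 3. In the other 8 libraries it was at most 1.71%. Without those 6 libraries, limma called 0 transcripts between SRA and CON under saline and 1007 had an unadjusted p under 0.05, with 2 males left in CON and 2 females in SRA. Under saline genotype then went with sex, so this fit does not tie the small p-values to those libraries.

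**Figure D3:**
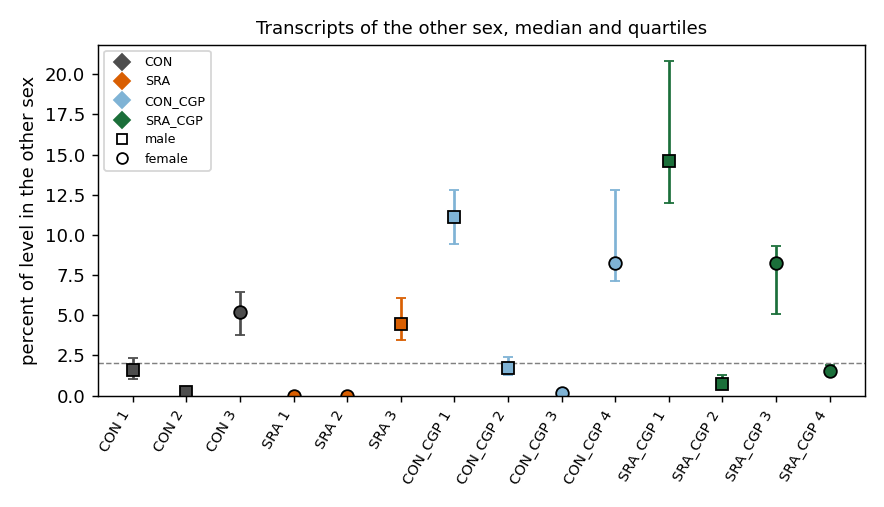
Level of transcripts of the other sex in each library (x axis), as a percent of their median level in that sex (y axis); points are medians and bars the quartiles over 12 male transcripts (in female libraries, circles) or 49 female transcripts (in male libraries, squares). The dashed line marks 2%, and the 6 libraries above it lie between 4.47% and 14.6%.

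Whether the agonist or the transgene acted differently in females and males was tested by their interactions with sex. limma called 0 transcripts for the agonist, with 3292 at an unadjusted p under 0.05 and a smallest adjusted p of 0.602. It called 0 for the transgene, with 2275 at an unadjusted p under 0.05 and a smallest adjusted p of 0.706. For the agonist the lower share was 71.6% as deposited, 38.9% after median-of-ratios rescaling and 38.8% after quantile normalization. For the transgene it was 42.7%, 39.4% and 19.1%. Single libraries moved these numbers. For the agonist, 10867 (88.5% lower) had an unadjusted p under 0.05 without CON_CGP replicate 1, 4946 without CON_CGP replicate 3, 2038 without SRA_CGP replicate 3, 1868 without SRA replicate 1 and 1738 without SRA replicate 3. For the transgene, it was 7537 (84.2% lower) without SRA replicate 3, 5671 (65.5% lower) without CON_CGP replicate 2, 1389 without CON replicate 3, 1364 without CON_CGP replicate 1 and 1312 without CON_CGP replicate 3. Without CON replicate 3, limma called 638 for the agonist. Without the 6 libraries the transgene by sex contrast rested on single libraries of each sex in the CGP groups, so its count is left out here and nothing is drawn from it.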

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

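The tests below of other splits of the samples, of the transcripts of the other sex and of those seen in SRA libraries alone were chosen after the results were seen. The rescaling, component and correlation tests, and, as the exception among the splits, that of small p-values for SRA against CON under saline without the block, were set before theirs. The criteria of the 2 correlation tests were widened after their values were seen: a value inside the middle 95% of regroupings had been set to count against the explanation. That bound was wrong, because regroupings with no real grouping reached 0.796 and 0.753, so a shared effect could lie inside that range.

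In groups of 4 libraries, 4 of 64 sets of values had 1 library far from the others, where chance gives 3.2. In CON_CGP replicate 1, uc007cav.1 was 2497 against 2093 to 2115 in the other 3 libraries, and uc011wph.1, nearly a copy of it, was 2481 against 2079 to 2101. In SRA_CGP replicate 3, uc009kba.1, a transcript that differed by sex, was 84 against 0 to 12. On the second principal component SRA_CGP replicate 4 was at -18.62 against 34.07 to 42.18. SRA_CGP replicate 4 was a female, and of the others only SRA_CGP replicate 3, at 41.9, was.

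The excess of small p-values between SRA and CON under saline (9138 transcripts, with 1998 by chance) was weighed. It fell to 2943 without CON replicate 3 (only males left in CON), 3896 without SRA replicate 3 (only females left in SRA) and 4932 without CON replicate 1. It rose to 10920 without CON replicate 2 and 11931 without SRA_CGP replicate 2, the highest without 1 library. Without the 6 libraries that held transcripts of the other sex it was 1007. The last fit kept only males in CON and only females in SRA, so it cannot show where the excess came from. Only 10 splits of the 6 saline libraries exist, too few for a share under 0.05. Of these 1, the real one, had as many, and the highest other had 4385. In the fit of those 6 libraries alone, 1 of 9 fitted splits, the real one, had as many as 9725 calls, and the highest other had 0. Total-count scaling as the whole cause of the number is argued against by the 7437 transcripts found after median-of-ratios rescaling. The direction turned, with 5367 higher and 2070 lower in SRA, against 2113 and 7025 as deposited. Many of the 7437 were therefore not the same transcripts in the same direction, and how many were shared was not counted. A transgene effect shared by both infusions stays open, as the log2 differences in the separate saline and CGP libraries had r = 0.524 across transcripts, which are not independent replicates, and 9 of 100 regroupings were as high.

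The spread along the first principal component was weighed next. Total-count scaling is argued against by a correlation of 0.993 between the components before and after quantile normalization. The share of each library taken by the 10 transcripts with the highest mean over all 14 libraries may be part of the spread. That share had Pearson r = 0.68 (permutation p = 0.0091, adjusted over 4 relations 0.0091) and Spearman rho = 0.71 (permutation p = 0.0054, adjusted 0.0072). Without the 2 farthest libraries r was 0.6 (permutation p = 0.043). The median value of a library was related more closely, with r = -0.8 (adjusted permutation p = 0.0017) and rho = -0.89 (adjusted 4e-04). Without its 2 farthest libraries r was -0.84. Sex may be part of the spread too, since 66.8% of the variance was left after sex was removed and 38.3% after group and sex. The sex test, however, missed the threshold after adjustment. The transgene stays open as a biological explanation, and differences in tissue makeup were not tested.

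Transcripts of the other sex at a few percent were weighed last. The highest median share was 14.6%. It cannot test for a wrong sex label, because the sets were chosen to be lower in every library labelled with the other sex. In a set chosen with no condition on the lowest library, the upper quartile of the lowest library was 0.712% of the lower quartile of the highest among females, which argues against low expression in every female, and 18.8% among males, where it stays open. RNA or reads from libraries of the other sex may be a source. Shares within each of the 6 libraries agreed to within a quartile ratio of 1.83. Where it could be taken in the others, this ratio ran from 1.36 in SRA_CGP replicate 4 to 3.2 in SRA_CGP replicate 2, so it does not set the 6 apart. In SRA replicate 3, 15 transcripts seen otherwise in SRA replicates 1 and 2 alone lay at 5.76% of their level there (quartiles 2.71 to 9.29), overlapping the 4.21% (2.9 to 6.23) of female transcripts. A first version, whose 8 transcripts had to reach 10 in SRA replicate 3 and so favoured high shares, gave 7.77% (6.81 to 13.1), which did not overlap; mixing between mice, tissue and sequencing cannot be separated here.

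Calls under other splits were as follows. Where the real count was 0, every split has at least as many, so the split count says nothing about chance. This holds for SRA against CON under saline (10 of 10 splits, highest other 0), CGP in CON (35 of 35, highest other 2) and CGP in SRA (35 of 35, highest other 6). It holds also for the interactions (100 of 100 each), with highest others of 7454 for agonist by transgene, 3016 for agonist by sex and 11994 for transgene by sex. By the number of transcripts at p under 0.05, chance cannot be excluded for CGP in CON (12 of 35 splits, real 1587, highest other 6633), CGP in SRA (8 of 35, real 2775, highest other 7931) or the same 3 interactions (41, 15 and 22 of 100). These splits ignored the replicate number, which met the criterion for pairing in CGP in SRA and in SRA against CON under saline. With the replicate block, the splits to compare are those that part all 3 pairs. For CGP in SRA these are 8, too few for a share under 0.05; 1, the real one, had as many as 15 calls (highest other 0), and 3 had as many small p-values (real 3555, highest other 6531). For SRA against CON under saline they are 4, also too few; 1, the real one, had as many as 532 calls (highest other 0), and its 10699 small p-values compare with a highest other of 781. Splits that part fewer pairs reached 8004 and 15300 small p-values. For SRA against CON under CGP it cannot be excluded by calls (3 of 35, real 1, highest other 9371) or by small p-values (13 of 35, real 2685, highest other 14411). For the averaged transgene contrast the share of regroupings with as many calls was under 0.05 (3 of 100, real 15, highest other 15402). The share with as many small p-values was too (3 of 100, real 11383, highest other 19386). This does not exclude chance, as the contrast was added afterwards, the shares are unadjusted over the comparisons, and the regroupings ignored the replicate number. Its small p-values fell to 5625 without CON replicate 3 (only males left in CON) and 6544 without SRA replicate 3 (only females left in SRA). They fell to 2066, where chance gives 1998, without the 6 libraries with transcripts of the other sex, which left only males in CON and only females in SRA. For sex the share was under 0.05 by calls, also unadjusted (2 of 100, real 2120, highest other 4471). It was not by small p-values (8 of 100, real 6387, highest other 11177). For the averaged agonist contrast the share was under 0.05 by calls (2 of 100, real 1, equalled by another split) and not by small p-values (23 of 100, real 2697, highest other 10769), and its single call was lost without each of 13 libraries, so little rests on it. Splits with far more calls than the real one point to a structure of the samples that the groups do not follow; the one with 9371 set CON_CGP replicate 1 and SRA_CGP replicates 1, 3 and 4 against the other 4 libraries.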

How the results depend on the processing

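The averaged transgene contrast and the fit without 6 libraries were chosen after the data were seen. Of 811 alternative values of named transcripts, 0 reversed, 707 kept their side of the threshold, 74 lost it and 30 gained it; of 250 alternative counts, 171 stayed within 1.5 times the main count and 79 moved, and the cause was not tested. Array weights called 8187 (SRA against CON, saline), 491 (CGP in CON), 53 (CGP in SRA), 3 (interaction), 2297 (SRA against CON under CGP), 5062 (averaged CGP), 5258 (sex) and 18467 (averaged transgene), but 3 of those fits stopped before the weights had converged, so these counts are given as values only; the tallies above include them. With no filter, counts were 12 (SRA against CON, saline), 21 (CGP in SRA) and 41 (averaged transgene); with a minimum mean of 50 they were 0 for SRA against CON under CGP, averaged CGP and averaged transgene, and this filter removed uc008qvw.2 and uc008uot.1 from the test. Without a sex term they were 0, 0 and 1 in the same order. The fit of the 2 groups alone called 9725 for SRA against CON under saline and 0 under CGP. For averaged CGP, pseudocounts of 5 and 0.2 and quantile normalization gave 0; for averaged transgene, a pseudocount of 0.2, both rescalings and moderation without the robust option gave 1. Without the 6 libraries, counts were 0 for SRA against CON under CGP, averaged CGP and averaged transgene, and 597 for sex. For transgene by sex the fit gave 2232, which is printed as a value only. That contrast then rested on single libraries of each sex in the CGP groups, without replicates, so nothing is drawn from it. Agonist by sex could not be fitted without the 6 libraries.

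Replicate numbers met the criterion for pairing only for SRA against CON under saline and CGP in SRA, and it cannot tell pairing from the sex layout. Over all groups 10 of 19 same-numbered pairs had a correlation of deviations above 0.1 and 5 of 14 libraries correlated best with their own number. With the replicate number as a block, counts were 532 (SRA against CON, saline), 15 (CGP in SRA), 0 (SRA against CON under CGP), 0 (averaged CGP) and 937 (averaged transgene). Leaving out 1 library at a time gave 0 to 13 (SRA against CON, saline; 13 without SRA replicate 3), 0 to 29 (CGP in SRA; 29 without SRA replicate 3), 0 to 1 (SRA against CON under CGP), 0 to 30 (averaged CGP; 30 without SRA replicate 3), 1554 to 2214 (sex), 0 to 638 (agonist by sex; 638 without CON replicate 3) and 1 to 4808 (averaged transgene; 1621 without CON replicate 2 and 4808 without SRA_CGP replicate 2). The count at p under 0.05 for SRA against CON under saline fell to 2943 without CON replicate 3, 3896 without SRA replicate 3 and 4932 without CON replicate 1. It rose to 10920 without CON replicate 2 and 11931 without SRA_CGP replicate 2. The fits without CON replicate 3 and without SRA replicate 3 left only males in CON and only females in SRA, respectively. edgeR and DESeq2 on whole reads, the B cell term and the gene list alternatives were not run, for want of whole reads and of gene names. Unknown depth limits how far low values such as those of uc008qvw.2 can be judged.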

Other observations

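The tests on transcripts seen in SRA libraries alone were chosen after the values were seen; the correlation test was set before its value, with its criterion widened afterwards. Under saline, 8 transcripts were at 10 or more in all 3 SRA libraries and at most 5 in the other 11. They lay between 73 and 409 in SRA replicate 1, between 91 and 542 in replicate 2 and between 10 and 25 in replicate 3. Of the 364 triples of libraries, 2 had as many transcripts of their own, and the highest other had 12. That set had to reach 10 in SRA replicate 3, which narrows its ratios, so the spread was taken over 15 transcripts at 50 or more in SRA replicates 1 and 2, at most 5 outside SRA and with no condition on replicate 3. The SD of their log2 ratios to replicate 1 was at most 0.76 times that of 11000 other transcripts at the same level. One outside source of RNA added in different amounts is a candidate explanation that this leaves open, as are effects in the mice.

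The log2 differences of CGP against saline in CON and in SRA had r = -0.037 across transcripts, which are not independent replicates, and 58 of 100 regroupings were as high, the highest at 0.753. A response shared by both genotypes may still exist, since a correlation over all transcripts has little power for a response of few of them.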
